A study of Mus musculus with 10 samples.

How the data were processed

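The series holds TCR sequencing libraries of splenic Treg cells from 10 mouse samples, 5 from CNS4KO and 5 from CNS4Flox mice, as the strain labels give them. Replicates were numbered within each group in the order of the samples. Per the labels' protocols, total RNA was extracted with TRIzol, reverse transcribed with primers for both TCR chains and a template switch adapter, and amplified in a pair of PCR steps. Libraries were pooled at equal molar ratios and sequenced on a NovaSeq, per the labels' protocols. The labels give at least 20x coverage relative to the number of Treg cells used, whereas deposited counts averaged 1.16 to 1.68 per TRB clonotype and 1.82 to 3.87 per TRA clonotype over the samples. The number of cells per sample, the aligner and the clonotype caller were not given in the sources used here.

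Each deposited table lists clonotypes of a single library. Per the file headers, the count of a clonotype is a whole number, and the fraction is the deposited count divided by the total count of the library over both chains, which held to rounding in every library. Whether counts are reads or molecules is not stated. The tables also give the CDR3 sequence, V, D and J gene names, and the positions where the matched V, D and J parts end or start, per the file headers. The labels name mm10 as the genome build. The tables held 754060 counts in 387286 entries, all in frame and without stop codons. Depth was 61793 to 95853 counts per sample, of which 19199 to 34833 were assigned to TRB and 40091 to 68224 to TRA.

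All entries carried TRBV and TRBJ names, although the protocol amplified both chains. The chain was therefore assigned here from the CDR3 amino acid end, requiring at least 4 residues that match the germline end of a TRBJ or TRAJ gene, from a list of J ends written from general knowledge with no reference sequence to check it against. TRB ends held 35.3% of counts, TRA ends 64.0%, and 0.728% matched neither and were left out. V, D and J names of TRA entries were not used, and TRA entries are those alpha chains that the caller listed under beta chain names. The J name matched the CDR3 end in 99.0% of TRB entries with a single possible J gene other than TRBJ1-6. The name TRBJ1-6 did not occur, and 6700 of the 6833 entries with its end were named TRBJ2-5; entries with that end were set apart as TRBJ1-6. TRB clonotypes were defined by V gene, J gene and CDR3 nucleotides, TRA clonotypes by J end and CDR3 nucleotides.

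Before richness, entropy and shares of abundant clonotypes were compared, samples were brought to the smallest total of the chain, 19199 for TRB and 40091 for TRA. Richness was the rarefied expectation, and the other values were means of 20 random draws. Overlap used amino acid clonotypes. Inserted bases were the bases between the V, D and J matches of TRB clonotypes. CDR3 length, cysteine, doublet and insertion values counted each distinct clonotype once. The invariant NKT alpha chain was counted by its CDR3 alone, since no alpha V name was used.

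Single values per sample were compared with two-sided exact permutation tests over the 252 assignments of 10 samples to the groups, whose smallest p is 0.00794, with Benjamini-Hochberg adjustment over 18 values and, separately, over 6 gene lists. Overlap was tested by permuting samples, not pairs. V and J gene counts and clonotype counts were compared with edgeR's quasi-likelihood test, without TMM and with the chain total as library size, for genes with at least 10 counts in at least 5 samples and for amino acid clonotypes detected in at least 5 samples. DESeq2 was run as an alternative with its own size factors. Intervals are 95% Wilson intervals. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0. Gene symbols and positions came from the RefSeq annotation of GRCm38, the assembly of mm10, in which 22 of 22 TRBV, 12 of 12 TRBJ and 31 of 31 TRAJ genes tested were found.

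Groups, tests, gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. Named V and J genes are, for each of TRBV, TRBJ and TRAJ, the 3 with the highest mean share, up to 10 past an adjusted p of 0.05 or otherwise the 2 with the smallest p, and all members of the TRBV lists. Named clonotypes are up to 5 per direction with the largest fold past the threshold and the 3 with the highest mean share among those in all 10 samples, of which TRB had only 2. The alternative settings fixed in advance were another clonotype definition, leaving out clonotypes with a count of 1, no thinning or deeper thinning, Chao1, weighting by count, other overlap indices, a filter on possible carry-over, other normalisations, tests and filters, and leaving out each sample in turn. Assigning chains by CDR3 ends and setting TRBJ1-6 apart were decided after the tables were seen.

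The procedures were tested on simulated data. Of 200 simulated sets without a difference, 4% gave an exact p of at most 0.05, and a true clonotype number at 95% of the other group's was called lower in 100% of 20 sets; all samples of a group in the latter sets had the same true clonotype number, without the spread between real samples, so they check the code and give no sensitivity for these data. To measure recovery, 4 of the 22 TRBV, 12 TRBJ or 31 TRAJ genes, or 200 of the 666 TRB or 7176 TRA clonotypes, were changed at once. The share changed differed between these sets, so recovery is not directly comparable between them. For TRBV genes, 55% of 1.25-fold, 90% of 1.5-fold and 100% of 2-fold changes were recovered. For TRBJ genes 100% were recovered at each of these folds, and for TRAJ genes 35%, 85% and 100%. The share of false calls, averaged over 5 simulated sets, was 6.67%, 14% and 4% for TRBV genes at these folds, 4%, 4% and 0% for TRBJ genes and 11.7%, 0% and 4% for TRAJ genes, against the 5% aimed at. For TRB clonotypes 0%, 69.1% and 99.5% of 4-fold, 16-fold and 64-fold changes were recovered, and for TRA clonotypes 0%, 6.8% and 82.2%. The shares of false calls were 0%, 5.19% and 6.56% for TRB and 0%, 1.18% and 2.59% for TRA clonotypes. Simulated counts were drawn from a fitted count model, so these shares need not hold for the real libraries. There, 100 of 100 drawn splits of the samples, the real one included, gave at least 9 TRA clonotypes past the threshold. Alpha V gene usage, alpha inserted bases, the lists of 3' TRAV genes, of genes shared by alpha and delta chains and of gamma, delta or immunoglobulin chains, and non-productive shares were not analysed here, since the entries give no alpha V genes, no such names and no non-productive sequences. The MAIT alpha chain was not analysed either.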

Results

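T cell receptor (TCR) alpha and beta transcripts were sequenced from splenic regulatory T (Treg) cells of 10 samples. The 5 CNS4KO samples came from mice lacking CNS4, an enhancer of Foxp3, the gene of the transcription factor that defines the Treg lineage. The 5 CNS4Flox samples came from mice carrying the floxed enhancer. The series states repertoire diversity as the purpose of the sequencing, and the design held this single comparison. Foxp3 itself (chromosome X, 7579676 to 7595243, mm10) was not measured here, so the deletion of its enhancer could not be checked in these libraries.

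The deposited counts summed to 95853, 69836, 73126, 75497 and 88070 in CNS4KO replicates 1 to 5. They summed to 65720, 72138, 79963, 61793 and 72064 in CNS4Flox replicates 1 to 5. Beta chain (TRB) counts were 27003, 19199, 25161, 34833 and 32269 in CNS4KO replicates 1 to 5, and 21670, 30838, 32979, 20854 and 21541 in CNS4Flox replicates 1 to 5. Alpha chain (TRA) counts were 68224, 50051, 47399, 40091 and 55131 in CNS4KO replicates 1 to 5, and 43605, 40741, 46378, 40547 and 50059 in CNS4Flox replicates 1 to 5. The total per sample was 80476 ± 11024 (SD, n = 5) in CNS4KO and 70336 ± 6950 (SD, n = 5) in CNS4Flox, with a two-sided exact permutation p of 0.127. A CNS4KO clonotype held 1.53 ± 0.138 TRB counts (SD, n = 5) and 3.10 ± 0.477 TRA counts (SD, n = 5) on average. A CNS4Flox clonotype held 1.24 ± 0.0712 TRB counts (SD, n = 5) and 2.09 ± 0.204 TRA counts (SD, n = 5), with an exact permutation p of 0.00794 for each chain. The chain of each clonotype was read from the end of its CDR3, the hypervariable loop formed where V and J genes join. TRA values describe the alpha chains listed under beta chain gene names, a subset whose share of all alpha chains is unknown. All p-values measure the spread between samples only, because the labels do not say whether replicates were separate mice.

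CNS4KO libraries held a less diverse repertoire than CNS4Flox libraries at equal counts, in both chains. The number of cells per sample was not given, so equal counts need not stand for equal numbers of cells. At 19199 TRB counts, CNS4KO samples held 13653 ± 980 distinct TRB clonotypes (SD, n = 5) and CNS4Flox samples 16190 ± 420 (SD, n = 5), a ratio of 0.843. At 40091 TRA counts, CNS4KO samples held 14351 ± 1378 distinct TRA clonotypes (SD, n = 5) and CNS4Flox samples 19730 ± 1631 (SD, n = 5), a ratio of 0.727. The Shannon entropy (natural log), a diversity index that also weighs evenness, was 9.23 ± 0.171 in CNS4KO against 9.60 ± 0.0523 in CNS4Flox for TRB (SD, n = 5 each). For TRA the entropy was 8.56 ± 0.272 in CNS4KO against 9.32 ± 0.206 in CNS4Flox (SD, n = 5 each).

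The most abundant clonotypes took more of the CNS4KO repertoire. The 100 most abundant TRB clonotypes held 9.05% ± 2.63 of the TRB counts in CNS4KO and 3.70% ± 0.880 in CNS4Flox (SD, n = 5 each). The 100 most abundant TRA clonotypes held 21.7% ± 4.50 of the TRA counts in CNS4KO and 11.6% ± 2.85 in CNS4Flox (SD, n = 5 each). The largest single TRB clonotype of a CNS4KO sample held 0.189% to 1.87% of its TRB counts, against 0.0738% to 0.415% in CNS4Flox samples. The largest single TRA clonotype held 0.841% to 2.99% of the TRA counts in CNS4KO samples and 0.259% to 1.26% in CNS4Flox samples.

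Richness and entropy of both chains, and the TRA share of the 100 most abundant clonotypes, separated the groups completely, all 5 CNS4KO samples lying beyond all 5 CNS4Flox samples. Each of these 5 comparisons gave a two-sided exact permutation p of 0.00794, the smallest that the 252 assignments of the samples can give, and an adjusted p of 0.0204 over 18 comparisons. The TRB share of the 100 most abundant clonotypes gave an exact p of 0.0159 and an adjusted p of 0.0357. In 4 of 5 CNS4KO samples that share exceeded every CNS4Flox sample, and the lowest CNS4KO sample, at 4.76%, lay below the highest CNS4Flox sample, at 5.08%. Over the alternative settings fixed in advance the adjusted p ranged from 0.0204 to 0.571 for TRB richness, 0.0204 to 0.536 for TRB entropy and 0.0179 to 0.0893 for the TRB share. For TRA it ranged from 0.0204 to 0.2 for richness and from 0.0204 to 0.0357 for both entropy and the share of the 100 most abundant clonotypes.

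TRB clonotypes with a count of 1 made up 74.4% of those in CNS4KO and 84.1% of those in CNS4Flox (exact permutation p = 0.0159), so leaving them out removed unequal shares of the groups. Without them the CNS4KO mean TRB richness was 275 higher (exact p = 0.381), and TRB entropy (exact p = 0.357), TRA richness (exact p = 0.111) and the TRB share (adjusted exact p = 0.0893) no longer passed. At full depth, TRB richness (exact p = 0.317), TRB entropy (adjusted exact p = 0.0893) and TRA richness (adjusted exact p = 0.0714) did not pass either. That setting leaves depth unequal, with mean TRB counts of 27693 in CNS4KO and 25576 in CNS4Flox and mean TRA counts of 52179 and 44266. More counts by themselves add distinct clonotypes, which works against a lower CNS4KO richness. The difference in the TRB share was 5.09, 5.37, 5.28 and 5.31 percentage points without CNS4Flox replicates 1, 2, 4 and 5 in turn, each with an adjusted exact p of 0.0536.

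**Figure D1:**
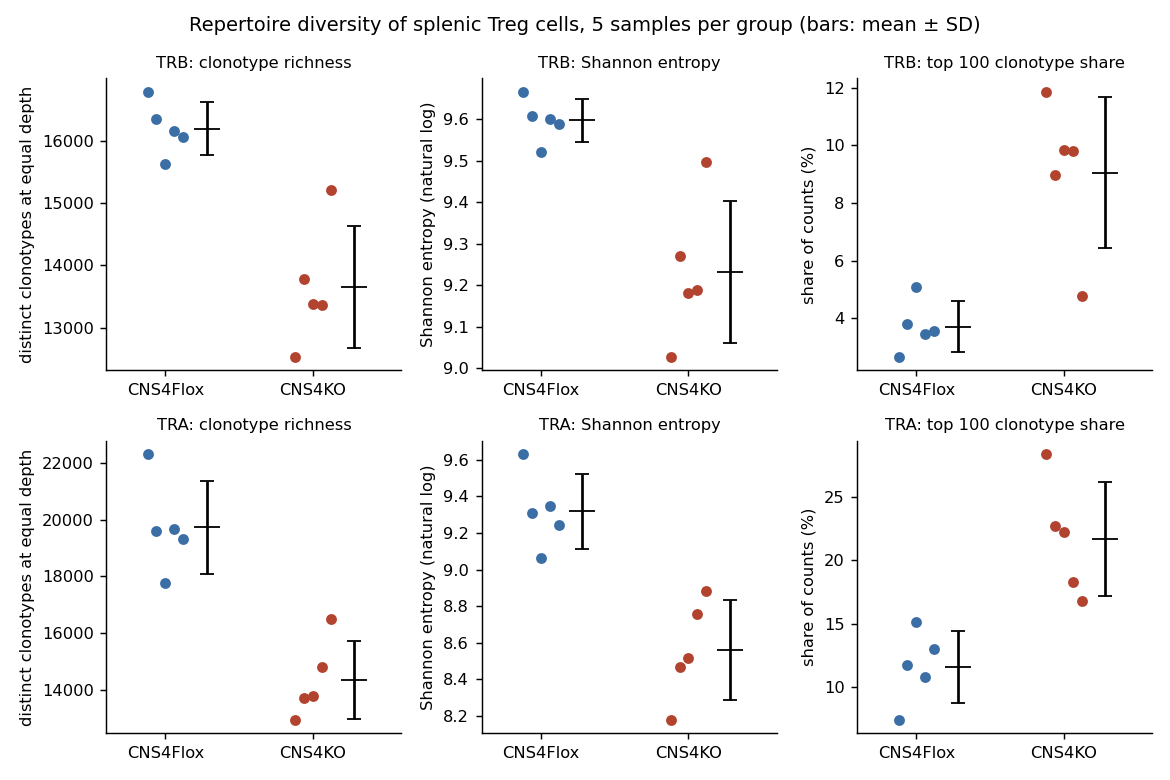
Distinct clonotypes at equal counts, Shannon entropy (natural log) and share of counts (%) of the 100 most abundant clonotypes, for TRB (top) and TRA (bottom). Each point is a sample, bars give mean ± SD of 5 samples, and the vertical axes do not start at 0; the groups overlap only in the TRB share, between 4.76% and 5.08%.

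By overlap indices, CNS4KO samples shared less of their alpha repertoire with each other than CNS4Flox samples did. Clonotypes found in at least 8 of the 10 samples nevertheless held 35.8% of TRA counts in CNS4KO and 36.0% in CNS4Flox. The mean Morisita-Horn overlap of TRA amino acid clonotypes, an index that is 0 without shared clonotypes and 1 for identical repertoires, was 0.105 among CNS4KO pairs (range 0.0525 to 0.195). It was 0.301 among CNS4Flox pairs (range 0.242 to 0.387) and 0.151 between the groups. With the Jaccard index, which ignores abundance, the means were closer, at 0.161 among CNS4KO pairs, 0.187 among CNS4Flox pairs and 0.171 between the groups (CNS4KO minus CNS4Flox -0.0266, exact permutation p = 0.00794, unadjusted). TRA clonotypes present in at least 3 of the 5 samples numbered 5024 in CNS4KO and 7289 in CNS4Flox at equal counts, and those present in all 5 numbered 1063 and 1875. These numbers and both indices were not adjusted for the lower number of distinct TRA clonotypes in CNS4KO, a ratio of 0.727 at equal counts. The Morisita-Horn index weighs abundant clonotypes most, and these held a larger share in CNS4KO. Its lower value therefore does not by itself show that fewer clonotypes were shared. Across all 10 samples 732 TRA clonotypes were shared at equal counts.

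The CNS4KO overlap was lower than the CNS4Flox overlap by a difference of -0.196 (exact permutation p = 0.00794, unadjusted). The mean overlap within groups exceeded that between groups by 0.0514 for TRA, with an exact permutation p of 0.00794 and an adjusted p of 0.0204, and this excess came with the CNS4Flox pairs, since the CNS4KO mean lay below the mean between groups. The difference in shared TRA clonotypes, -2265, had the same exact p and adjusted p. Over the alternative settings fixed in advance the adjusted p ranged from 0.0204 to 0.214 for the TRA overlap and from 0.0204 to 0.0357 for the shared TRA clonotypes. Without CNS4Flox replicate 1 the difference in shared TRA clonotypes was -1504 (adjusted exact p = 0.0357), with at least 3 of 4 samples then required in each group. The TRA overlap within groups exceeded that between groups by 0.0189, 0.0252, 0.0333, 0.0233 and 0.0336 without CNS4Flox replicates 1 to 5 in turn, with adjusted exact p from 0.111 to 0.214, and by 0.00259 with the Jaccard index (adjusted exact p = 0.175). Leaving out a CNS4Flox sample leaves fewer CNS4Flox than CNS4KO pairs in the pooled mean within groups, which by itself lowers this excess.

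TRB repertoires overlapped little, with means of 0.0113 among CNS4KO pairs, 0.0339 among CNS4Flox pairs and 0.0221 between the groups. The TRB excess within groups was 0.000528 (exact p = 1), and the difference between CNS4KO and CNS4Flox pairs was -0.0225 (exact p = 0.111). TRB clonotypes in at least 3 of 5 samples numbered 493.5 in CNS4KO and 608.7 in CNS4Flox (exact p = 0.0476, adjusted p = 0.0952, range over the alternative settings fixed in advance 0.0952 to 1). This difference, -115, was -75.4 to -39.6 with 1 sample left out in turn, when at least 3 of 4 samples were required in each group, and did not pass without any of them. In all 5 samples of a group there were 14.3 TRB clonotypes in CNS4KO and 14 in CNS4Flox. CNS4Flox replicate 3 and CNS4KO replicate 5 had the highest TRB overlap of any pair, 0.122, and shared 821 TRB nucleotide clonotypes, against 96 to 262 in the other 44 pairs. With 1 sample left out in turn, the TRB excess within groups ranged from -0.00411 to 0.0101. It was highest, and passed, without CNS4KO replicate 5 (0.0101, adjusted exact p = 0.0179). It did not pass without CNS4Flox replicate 3, which removes the same pair. Leaving out a CNS4KO sample also leaves fewer CNS4KO than CNS4Flox pairs in the pooled mean within groups, which by itself raises the excess. Without both libraries of this pair, TRB and TRA richness differed by -3066 and -6411, TRB and TRA entropy by -0.450 and -0.900, and the TRB and TRA shares of the 100 most abundant clonotypes by 6.77 and 12.2 percentage points. The shared TRA clonotypes then differed by -2057 and the TRA overlap within groups exceeded that between groups by 0.0615. Groups of 4 allow no exact p below 0.0286, so that the adjusted p was 0.0643 for each of these 8 values.

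**Figure D2:**
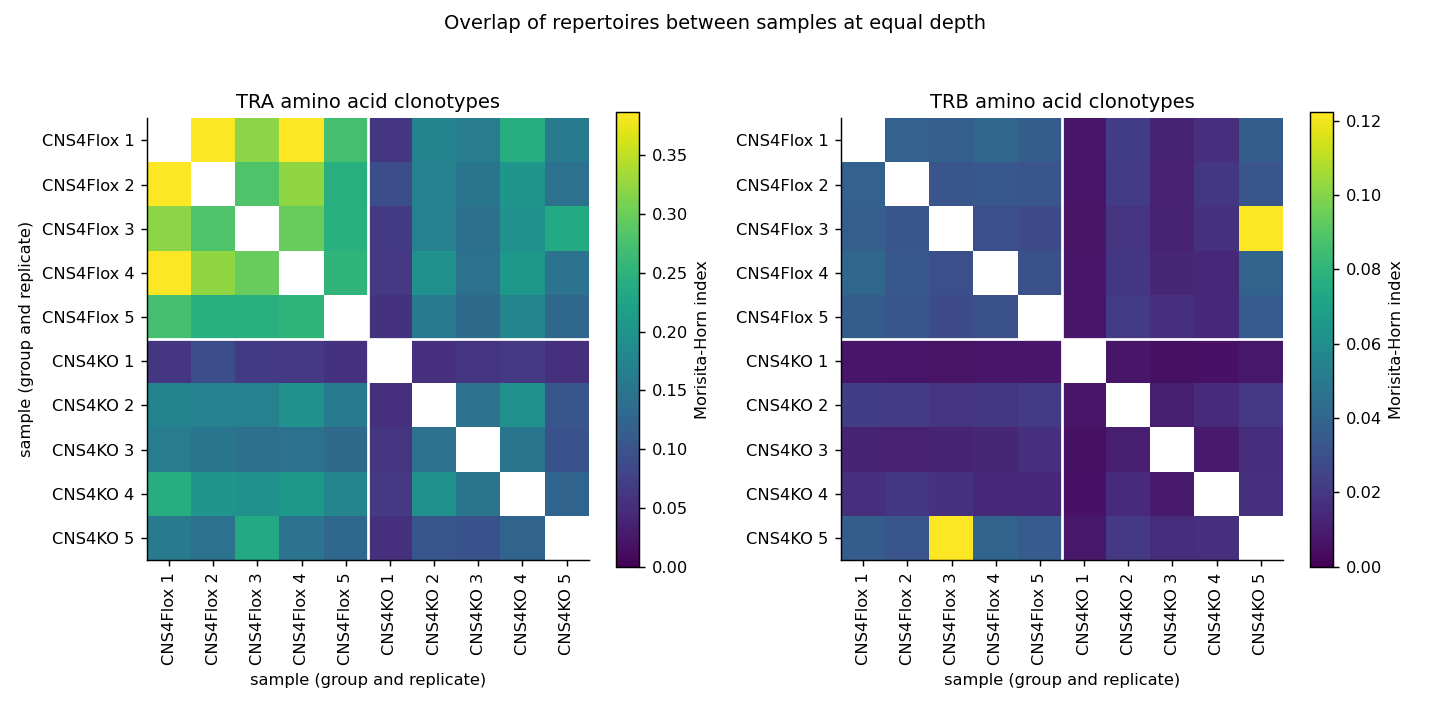
Morisita-Horn overlap of amino acid clonotypes for each pair of samples, TRA left and TRB right, with colour scales from 0 and white lines between the groups. CNS4Flox pairs had TRA overlaps of 0.242 to 0.387 and CNS4KO pairs 0.0525 to 0.195, and the brightest TRB cell is the pair of CNS4Flox replicate 3 and CNS4KO replicate 5, at 0.122.

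**Figure D3:**
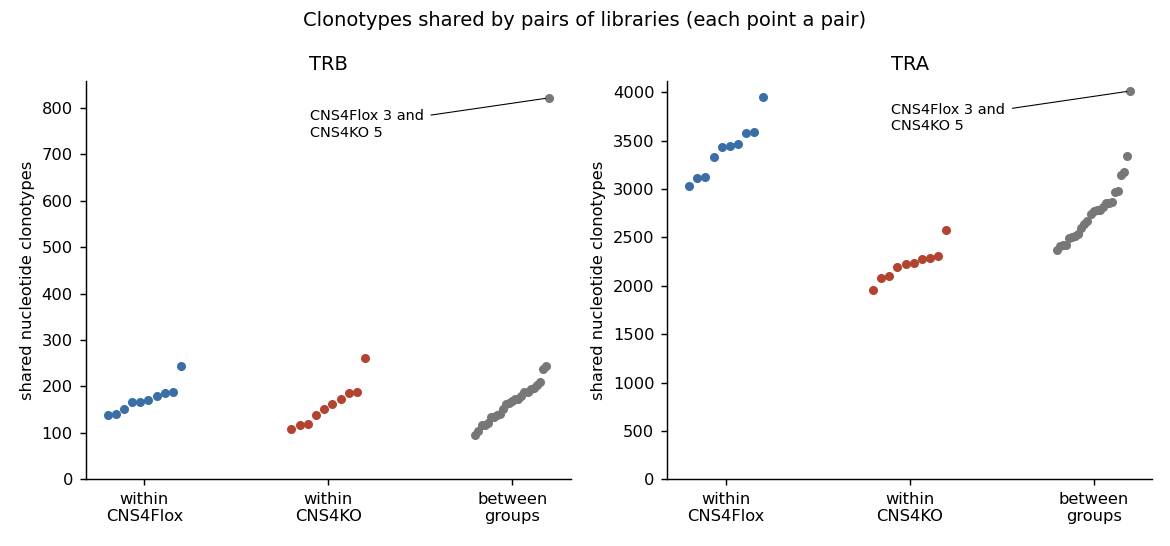
Nucleotide clonotypes shared by each of the 45 pairs of libraries at full depth, TRB left and TRA right, by whether the pair lies within or between groups. CNS4Flox replicate 3 and CNS4KO replicate 5 shared 821 TRB and 4012 TRA clonotypes, the highest number for each chain. The other pairs shared 96 to 262 TRB and 1960 to 3954 TRA clonotypes.

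No single TRBV gene differed between CNS4KO and CNS4Flox past the threshold by counts in edgeR. TRBV31 was the most used V gene, with 13.1% ± 2.55 of TRB counts in CNS4KO and 12.4% ± 0.978 in CNS4Flox (SD, n = 5 each). TRBV19 held 7.51% ± 1.46 and 7.23% ± 0.772, and TRBV26 held 6.16% ± 1.30 and 5.76% ± 0.524 (SD, n = 5 each). The V gene with the smallest p was TRBV12-1 (Vbeta5.2; chromosome 6, 41113567 to 41114067, mm10), with 6.55% ± 0.664 of TRB counts in CNS4KO and 5.11% ± 0.410 in CNS4Flox (SD, n = 5 each). Its near-identical paralog TRBV12-2 (Vbeta5.1; chromosome 6, 41118864 to 41119364) held 3.52% ± 0.186 and 3.06% ± 0.352 (SD, n = 5 each), and counting may split transcripts between the paralogs.

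In edgeR's quasi-likelihood test 0 of 22 TRBV genes passed an adjusted p of 0.05, with 1 gene, TRBV12-1, at an unadjusted p under 0.05. TRBV12-1 had a log2 fold change of 0.36 (SE 0.11), an adjusted p of 0.0653 in edgeR, and a higher share in all 5 CNS4KO samples than in any CNS4Flox sample. In DESeq2 1 TRBV gene passed, TRBV12-1 (adjusted p = 0.0185). Over all alternatives its adjusted p ranged from 0.00279 to 0.345. TRBV12-2 had a log2 fold change of 0.20 (SE 0.11) with an adjusted p of 0.644 in edgeR, and its adjusted p ranged from 0.0457 to 0.880.

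Counting each distinct TRB clonotype once, which sets aside how far a clonotype had expanded, 3 TRBV genes passed in edgeR. TRBV12-1 rose from 5.24% ± 0.401 of distinct clonotypes in CNS4Flox to 6.91% ± 0.422 in CNS4KO (SD, n = 5 each; log2 fold change 0.40, adjusted p = 0.00279). TRBV12-2 rose from 3.19% ± 0.333 to 3.82% ± 0.250 (SD, n = 5 each; log2 fold change 0.26, adjusted p = 0.0457 in edgeR). TRBV29 (Vbeta7; chromosome 6, 41271403 to 41271881, annotated as a pseudogene segment) was lower in CNS4KO, at 3.02% ± 0.119 of distinct clonotypes against 3.53% ± 0.148 (SD, n = 5 each; log2 fold change -0.23, adjusted p = 0.0198 in edgeR). For each of these 3 genes all 5 CNS4KO samples lay beyond all 5 CNS4Flox samples. For TRBV29 the adjusted p ranged from 0.0198 to 0.880 over all alternatives. Without CNS4KO replicate 4, 2 TRBV genes passed by counts in edgeR, TRBV12-1 (log2 fold change 0.40, adjusted p = 0.0156) and TRBV20 (log2 fold change -0.44, adjusted p = 0.0179), TRBV20 being named after its values were seen.

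A list of TRBV genes whose receptors can react with endogenous retroviral superantigens, which need not be complete, held TRBV12-1, TRBV12-2, TRBV15 and TRBV16. Together they held 20.7% ± 0.605 of TRB counts in CNS4KO and 19.8% ± 1.07 in CNS4Flox (SD, n = 5 each, exact p = 0.135, adjusted p = 0.286 over 6 lists). Of these 4 genes, 2 had higher and 2 lower fitted shares in CNS4KO; 0 passed over all genes tested in edgeR and 1, TRBV12-1, passed adjusted over the list alone (edgeR adjusted p = 0.0119). TRBV15 held 5.45% ± 0.643 in CNS4KO and 6.04% ± 0.696 in CNS4Flox, and TRBV16 5.15% ± 0.630 and 5.55% ± 0.486 (SD, n = 5 each). TRBV genes frequent in invariant NKT cells, an innate-like T cell population (TRBV1, TRBV13-2 and TRBV29), held 14.2% ± 0.920 in CNS4KO and 14.99% ± 0.604 in CNS4Flox (SD, n = 5 each; exact p = 0.0952, adjusted p = 0.286). TRBV genes frequent in mucosal-associated invariant T (MAIT) cells (TRBV13-1, TRBV13-2, TRBV13-3 and TRBV19) held 21.6% ± 1.61 in CNS4KO and 22.9% ± 0.740 in CNS4Flox (SD, n = 5 each; exact p = 0.143, adjusted p = 0.286). The NKT list had 0 genes higher and 3 lower, and the MAIT list 1 higher and 3 lower, by fitted share of counts; in each, 0 passed over all genes tested in edgeR or in DESeq2 and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05. By distinct clonotypes TRBV13-2 was higher in CNS4KO (6.18% against 5.82%), the MAIT list had 2 genes higher and 2 lower and differed by 0.0902 percentage points (exact p = 0.873) against -1.26 by counts, and the NKT list had 1 higher and 2 lower and differed by -0.294 (exact p = 0.476) against -0.840 by counts.

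Among the other members of these lists, TRBV1 held 5.71% ± 0.804 of TRB counts in CNS4KO and 5.90% ± 0.353 in CNS4Flox, and TRBV13-2 held 4.92% ± 0.522 and 5.25% ± 0.349 (SD, n = 5 each). TRBV29 held 3.52% ± 0.364 and 3.84% ± 0.234, TRBV13-1 held 5.11% ± 0.636 and 5.88% ± 0.580, and TRBV13-3 held 4.05% ± 0.760 and 4.50% ± 0.502 (SD, n = 5 each). The 22 TRBV genes lie between 40891296 and 41558371 on chromosome 6, and the 12 TRBJ genes between 41533864 and 41543856 (mm10).

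J gene usage showed no gene past the threshold in either chain by counts in edgeR. TRBJ2-7 held 18.8% ± 1.44 of TRB counts in CNS4KO and 19.3% ± 0.921 in CNS4Flox, TRBJ2-5 held 12.6% ± 0.558 and 12.8% ± 0.202, and TRBJ2-4 held 11.8% ± 0.335 and 12.2% ± 0.650 (SD, n = 5 each). TRBJ1-6 (chromosome 6, 41535554 to 41535606) held 3.80% ± 0.210 in CNS4KO and 3.44% ± 0.141 in CNS4Flox, and TRBJ1-5 held 2.60% ± 0.163 and 2.76% ± 0.156 (SD, n = 5 each). The TRBJ2 cluster as a whole, 1 gene with a higher and 5 with a lower fitted share, held 68.0% ± 1.65 in CNS4KO and 69.0% ± 1.253 in CNS4Flox (SD, n = 5 each; exact p = 0.357, adjusted p = 0.536). In edgeR 0 of 12 TRBJ genes passed and 1, TRBJ1-6 (log2 fold change 0.14, adjusted p = 0.129), was at an unadjusted p under 0.05; of the TRBJ2 genes 0 passed over all genes tested and 0 adjusted over the list alone. In DESeq2 1 TRBJ gene passed, TRBJ1-6 (adjusted p = 0.0282), whose adjusted p ranged from 0.0282 to 0.768 over all alternatives and whose share in 4 of 5 CNS4KO samples exceeded every CNS4Flox sample. Without CNS4KO replicate 4, 1 TRBJ gene, TRBJ1-6, passed in edgeR (log2 fold change 0.17, adjusted p = 0.0480).

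Along the TRAJ genes (chromosome 14, 54157280 to 54217901, mm10), whose order reflects successive rounds of alpha chain rearrangement in the thymus, no gene differed between CNS4KO and CNS4Flox past the threshold by counts in edgeR or DESeq2. Only alpha chains that the caller listed under beta chain names entered, with a median of 6 matched J bases against 18 for TRB. Which TRAJ genes appear, and their shares, may depend on that matching and need not stand for all alpha chains. TRAJ31 held 7.74% ± 1.19 of TRA counts in CNS4KO and 7.62% ± 0.283 in CNS4Flox, TRAJ12 held 5.59% ± 0.566 and 5.45% ± 0.121, and TRAJ30 held 5.38% ± 0.718 and 5.25% ± 0.259 (SD, n = 5 each). TRAJ40 (54177921 to 54177981) held 5.56% ± 0.311 in CNS4KO and 4.79% ± 0.370 in CNS4Flox (SD, n = 5 each; log2 fold change 0.22, adjusted p = 0.564 in edgeR, range 0.224 to 0.907 over all alternatives). TRAJ58 (54157280 to 54157342) held 0.454% ± 0.0679 in CNS4KO and 0.578% ± 0.0506 in CNS4Flox (SD, n = 5 each; log2 fold change -0.35, adjusted p = 0.564 in edgeR, range 0.158 to 0.953 over all alternatives). V-proximal TRAJ genes held 18.9% ± 1.06 in CNS4KO and 19.1% ± 0.661 in CNS4Flox (SD, n = 5 each; exact p = 0.683, adjusted p = 0.819), and the TRAJ genes at the 3' end held 33.9% ± 1.76 and 33.99% ± 0.904 (SD, n = 5 each; exact p = 0.921). The mean TRAJ number of distinct clonotypes was 30.2 ± 0.329 in CNS4KO and 30.2 ± 0.168 in CNS4Flox (SD, n = 5 each; exact p = 1).

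In edgeR 0 of 31 TRAJ genes passed by counts, with 2 at an unadjusted p under 0.05, and in DESeq2 0 passed. Each of the TRAJ lists had 10 genes tested, 4 with a higher and 6 with a lower fitted share; 0 passed over all genes tested and 0 adjusted over the list alone. Counting each distinct clonotype once, 1 TRAJ gene passed in edgeR, TRAJ32 (chromosome 14, 54186101 to 54186166; log2 fold change 0.19, adjusted p = 0.0319; higher in all 5 CNS4KO samples than in any CNS4Flox sample), named after its values were seen. By counts TRAJ32 held 1.99% in CNS4KO and 1.84% in CNS4Flox, with an adjusted p of 0.830 in edgeR.

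**Figure D4:**
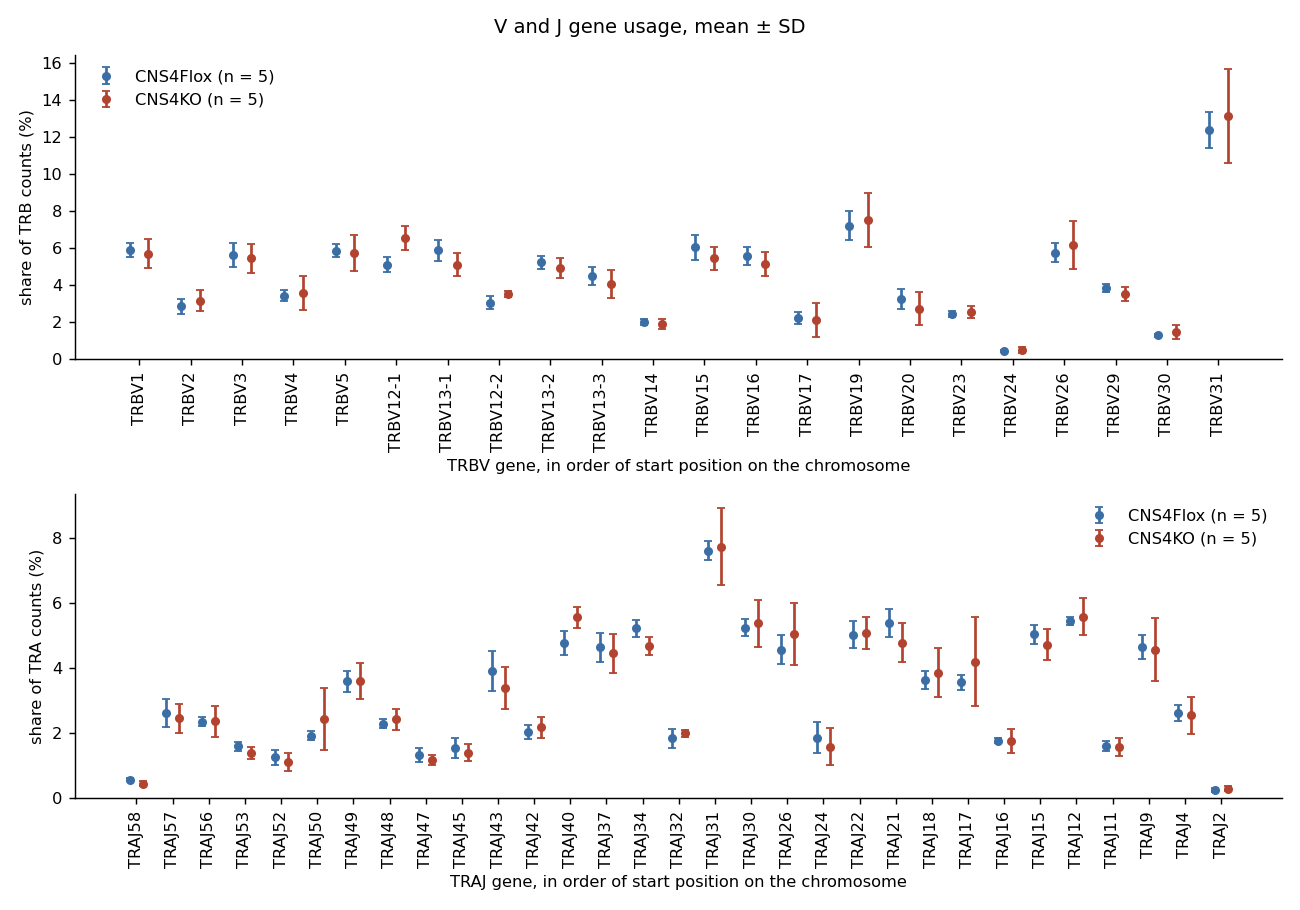
Share of counts (%) of each tested TRBV gene (top) and TRAJ gene (bottom) in order of start position, as mean ± SD of 5 samples per group, with axes from 0. TRBV12-1, at 6.55% in CNS4KO and 5.11% in CNS4Flox, has the smallest p of the TRBV genes.

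With all clonotypes included, no CDR3 feature linked to Treg selection differed between the groups past the threshold. TRB CDR3s averaged 13.7 ± 0.0299 residues in CNS4KO and 13.7 ± 0.0107 in CNS4Flox (SD, n = 5 each; exact p = 0.540). TRA CDR3s averaged 13.6 ± 0.0119 and 13.6 ± 0.0128 residues (SD, n = 5 each), a difference of 0.0115 (exact p = 0.175). A cysteine within the CDR3, after its first residue, was present in 5.85% ± 0.638 of CNS4KO and 5.97% ± 0.321 of CNS4Flox TRB clonotypes (SD, n = 5 each; exact p = 0.667). This value mostly restates TRBV1 usage, since 99.6% of TRBV1 entries began with CTC and TRBV1 made up 5.70% and 5.84% of distinct TRB clonotypes; with TRBV1 left out, a setting added after the data were seen, the share was 0.171% ± 0.0447 and 0.163% ± 0.0260 (SD, n = 5 each; exact p = 0.778). For TRA the cysteine share was 0.321% ± 0.0607 and 0.282% ± 0.0443 (SD, n = 5 each; exact p = 0.278). A hydrophobic doublet at CDR3 residues 6 and 7, a feature that favours self-reactivity, was present in 1.34% ± 0.0688 of CNS4KO and 1.32% ± 0.0475 of CNS4Flox TRB clonotypes (SD, n = 5 each; exact p = 0.548). TRB junctions held 3.85 ± 0.0635 inserted bases in CNS4KO and 3.83 ± 0.0181 in CNS4Flox (SD, n = 5 each; exact p = 0.460).

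Among these CDR3 features 0 of 6 passed the adjusted threshold in the exact permutation tests, and 0 of 6 had an unadjusted exact p under 0.05. Without TRA clonotypes of a count of 1, TRA CDR3s were longer in CNS4KO by 0.0398 residues and passed (adjusted exact p = 0.0179, range over the alternative settings fixed in advance 0.0179 to 1).

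The receptor of invariant NKT cells, which a Treg sort could carry over, was a small part of every sample. Its alpha chain CDR3 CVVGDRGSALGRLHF held 0.201% ± 0.0411 of TRA counts in CNS4KO and 0.148% ± 0.0495 in CNS4Flox (SD, n = 5 each; exact p = 0.111, adjusted p = 0.2). It was counted 69 to 135 times in CNS4KO samples and 42 to 89 times in CNS4Flox samples. The MAIT alpha chain was not analysed here.

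No TRB clonotype shared across samples differed between CNS4KO and CNS4Flox past the threshold. Of the 666 TRB amino acid clonotypes detected in at least 5 samples, 0 passed in edgeR, with 37 at an unadjusted p under 0.05, and 0 passed in DESeq2. The TRB clonotypes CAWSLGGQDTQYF of TRBV31 and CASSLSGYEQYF of TRBV26 were present in all 10 samples at full depth. They held 0.0156% ± 0.0103 and 0.0117% ± 0.00918 of TRB counts in CNS4KO, and 0.0107% ± 0.00589 and 0.00749% ± 0.00426 in CNS4Flox (SD, n = 5 each). In simulated sets of these 666 clonotypes, with 200 of them changed at once, 0% of 4-fold changes and 69.1% of 16-fold changes were recovered. Recovery of a single changed clonotype was not simulated.

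Among 7176 TRA clonotypes 9 passed in edgeR, 5 higher and 4 lower in CNS4KO, with 619 at an unadjusted p under 0.05, and in DESeq2 13 passed, 2 of them among these 9. The 9 cannot be separated from chance, since 100 of 100 drawn splits of the samples, the real one included, gave at least 9 in edgeR. In 8 of the 9, a single library held 74.5% to 99.1% of the share of the clonotype summed over the 10 samples. The clonotype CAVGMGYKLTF of TRAJ9 held 2.85% of TRA counts in CNS4KO replicate 1 (95% Wilson interval 2.72% to 2.97%), 99.1% of its share summed over samples, and was detected in 3 of 5 samples of each group. Its log2 fold change was 7.41 (SE 1.47), with an adjusted p of 0.0105 in edgeR, and -0.07 without CNS4KO replicate 1. The interval, like the others given here, covers counting error only, since the sources do not state whether molecular identifiers were used.

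CNS4KO replicate 1 also held 96.0% of the summed share of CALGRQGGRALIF of TRAJ15 (log2 fold change 7.19, adjusted p = 0.0105 in edgeR) and 97.8% of that of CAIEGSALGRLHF of TRAJ18 (5.59, adjusted p = 0.0433 in edgeR). Without CNS4KO replicate 1 their log2 fold changes were 2.68 and -1.67. CNS4KO replicate 2 held 97.8% of that of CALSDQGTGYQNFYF of TRAJ49 (log2 fold change 6.25, adjusted p = 0.0281 in edgeR), whose log2 fold change without this library was 0.52. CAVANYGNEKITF of TRAJ48 (log2 fold change 5.13, adjusted p = 0.0433 in edgeR) was the exception, at 0.721% in CNS4KO replicate 2 (95% Wilson interval 0.651% to 0.799%) and 0.536% in CNS4KO replicate 4, against a mean of 0.00691% in CNS4Flox. It did not pass with TMM normalisation (log2 fold change 5.29, adjusted p = 0.0674 in edgeR), among clonotypes detected in at least 8 samples (5.13, 0.256), without CNS4KO replicate 2 (4.24, 0.0612) or without CNS4Flox replicates 1, 2, 3 and 4 in turn (4.82 to 5.15, 0.0517 to 0.0962). The CNS4KO samples above the CNS4Flox mean numbered 3 for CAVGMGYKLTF, 4 for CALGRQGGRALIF, 4 for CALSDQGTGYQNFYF, 1 for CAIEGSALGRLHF and 2 for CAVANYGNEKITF, each out of 5.

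The 4 TRA clonotypes lower in CNS4KO had their largest shares in CNS4Flox replicates 2 and 5. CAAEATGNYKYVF of TRAJ40 (log2 fold change -5.78, adjusted p = 0.0333 in edgeR) and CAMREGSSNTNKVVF of TRAJ34 (-5.03, adjusted p = 0.0433 in edgeR) had 97.3% and 74.5% of their summed shares in CNS4Flox replicate 5. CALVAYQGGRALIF of TRAJ15 (-5.33, adjusted p = 0.0353 in edgeR) and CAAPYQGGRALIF of TRAJ15 (-4.73, adjusted p = 0.0433 in edgeR) had 93.0% and 88.5% in CNS4Flox replicate 2. The CNS4Flox samples above the CNS4KO mean numbered 2 for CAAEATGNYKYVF, 5 for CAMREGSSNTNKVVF, 5 for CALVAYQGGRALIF and 4 for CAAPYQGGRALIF, each out of 5. Without CNS4Flox replicate 5 the log2 fold changes of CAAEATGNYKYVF and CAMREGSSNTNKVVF were 0.29 and -3.29, and without CNS4Flox replicate 2 those of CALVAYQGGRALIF and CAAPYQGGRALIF were -1.39 and -1.51. The number of TRA clonotypes past the threshold was 31, 54, 49 and 54 without CNS4KO replicates 1, 3, 4 and 5 in turn, 14 without CNS4Flox replicate 3, and 42 without both libraries of the pair sharing many clonotypes. It was 3 with TMM normalisation, and 0 among clonotypes detected in at least 8 samples.

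The TRA clonotypes with the highest mean shares among those in all 10 samples did not pass. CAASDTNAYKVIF of TRAJ30 held 0.183% ± 0.0943 of TRA counts in CNS4KO and 0.358% ± 0.208 in CNS4Flox, and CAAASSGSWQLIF of TRAJ22 held 0.176% ± 0.0477 and 0.258% ± 0.133 (SD, n = 5 each). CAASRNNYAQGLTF of TRAJ26 held 0.410% ± 0.854 and 0.0281% ± 0.00442 (SD, n = 5 each; log2 fold change 3.85, adjusted p = 0.115 in edgeR, range 0.00937 to 0.997 over all alternatives), with 88.5% of its summed share in CNS4KO replicate 3. It passed without CNS4KO replicates 1, 4 and 5 in turn, with log2 fold changes of 4.16, 4.13 and 4.16, and its log2 fold change without CNS4KO replicate 3 was -0.03 (adjusted p = 0.997 in edgeR).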

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

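Of the tests in this part, those of material passing between a pair of libraries and of exchanged sample tags were chosen only after the result was seen, as was the limit of 5% of the difference between groups, below which a setting was taken to have moved nothing. Chance singles out about 1 in 20 groups of samples; 84 groups were examined, 4.2 would be expected by chance and 3 were found.

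Libraries of CNS4KO samples had lower richness and a higher share of abundant clonotypes at equal counts in both chains. The tables argue against a few expanded clonotypes as the whole cause of the lower richness, since without the 100 most abundant clonotypes, at the lower equal depths of 17476 TRB and 32758 TRA counts, richness was 13525 in CNS4KO against 15294 in CNS4Flox for TRB and 14601 against 18592 for TRA (exact permutation p = 0.00794 for each chain, the smallest possible), although the difference was smaller than with all clonotypes, by 30.3% for TRB and 25.8% for TRA. Sequence errors stay open: clonotypes that differ by 1 base from an abundant one were only 0% to 0.106% of TRB and 1.98% to 3.73% of TRA clonotypes with a count of 1, and leaving them out took the richness difference from -2537 to -2538 for TRB and from -5378 to -5329 for TRA, so that the criterion set in advance, an exact p under 0.05 (it was 0.00794 for each chain), was bound to be met and decides nothing. Fewer cells stay open in both chains: CNS4Flox libraries thinned to the CNS4KO mean richness had shares of at most 15.2% for TRA and 5.13% for TRB, against lowest CNS4KO samples at 16.8% and 4.76%, but thinning moved the mean CNS4Flox share by only 1.20% (TRA) and 2.21% (TRB) of the difference between groups, so that the criterion set in advance, every thinned library below the lowest CNS4KO sample, repeats the comparison without thinning. Cell numbers were not given in the sources used here, and thinning counts does not model the loss of whole cells. Average counts of 1.16 to 3.87 per clonotype, against the labels' coverage of at least 20x, leave open what a count stands for. Expansion beyond the 100 most abundant clonotypes was not tested separately. The lower richness may come from fewer sorted cells, from fewer Treg clones in CNS4KO mice, from a mixture of these, or from causes not tested here.

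CNS4Flox replicate 3 and CNS4KO replicate 5 shared 821 TRB nucleotide clonotypes, and 722 of these were in no other library, holding 5.39% of the TRB counts of CNS4Flox replicate 3 (95% Wilson interval 5.15% to 5.64%) and 3.75% of those of CNS4KO replicate 5 (3.55% to 3.97%). Exchange of sample tags among all libraries is argued against for TRB by the other pairs, which shared at most 262. For TRA the pair shared 4012 clonotypes and the other pairs 1960 to 3954, so the pair hardly stood apart by that number. Independent rearrangement is argued against by the 8.89 bases between V and J of the shared clonotypes, since the means in the other pairs were at most 7.42. Material of CNS4Flox replicate 3 in the library of CNS4KO replicate 5 remains a candidate explanation: 30 of the 100 most abundant TRB clonotypes of the former were found in the latter, against 6 in the other direction and 0 to 4 in the other ordered pairs. For TRA these numbers were 88, 34 and 8 to 42. The pair shared 1179 TRA clonotypes found in no other library, against at most 552 in the other pairs. They held 15.7% of the TRA counts of CNS4Flox replicate 3 (15.4% to 16.05%) and 6.75% of those of CNS4KO replicate 5 (6.54% to 6.96%). No other biological explanation was tested.

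The 9 TRA clonotypes past the threshold in edgeR cannot be separated from chance: 100 of 100 drawn splits of the samples into groups of 5 gave at least as many. The highest of the other splits gave 89, which points to a structure of the samples or to expansions in single libraries, since 1 library held 74.5% to 99.1% of the summed share in 8 of the 9; neither was tested. For gene usage by counts and for TRB clonotypes the real count was 0, so that all 100 splits gave as many by construction, which says nothing about chance; the highest other split gave 3 TRBV genes, 1 TRBJ gene, 3 TRAJ genes and 0 TRB clonotypes. By distinct clonotypes 3 TRBV genes passed, and 2 of 100 splits, the real one included, gave as many (highest other 3). This does not exclude chance, because it makes no allowance for the choice among settings. The 15 alternatives fixed in advance gave 0 to 3 TRBV genes, and this one gave the most.

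The share of the MAIT-associated TRBV genes was 21.6% in CNS4Flox replicate 4 (95% Wilson interval 21.01% to 22.1%), far below the 23.01% to 23.4% of the other CNS4Flox samples. TRBV26 held 6.69% of TRB counts in CNS4Flox replicate 4 (6.36% to 7.04%), far above the 5.46% to 5.64% of the other CNS4Flox samples. TRAJ40 held 5.03% of TRA counts in CNS4KO replicate 2 (4.84% to 5.22%), far below the 5.56% to 5.78% of the other CNS4KO samples. CDR3s whose end matched neither chain, which entered no comparison, held 0.728% of all counts, with 571 of these 3990 entries ending in QTYF.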

How the results depend on the processing

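The whole gap between V and J, the J names as deposited, the TRB cysteine share without TRBV1, and leaving out both libraries of the pair sharing many clonotypes were alternatives chosen after seeing the data; all others were fixed in advance. Leaving out 1 sample gave 290 values for the results tested, of which 255 counted as unchanged, 9 became weaker, 8 stronger and 18 changed direction. For a difference, unchanged meant the same direction and side of the threshold. For a number of genes or clonotypes past the threshold, it meant a similar number, whichever ones passed. Thus the 13 TRA clonotypes in DESeq2, 2 of them among the 9 in edgeR, counted as unchanged. The other settings fixed in advance gave 82 values, of which 61 counted as unchanged and 7 changed direction. The added ones gave 32, of which 21 counted as unchanged and 2 changed direction. Of these 27 changes of direction, only that in TRB richness concerned a difference past the threshold. Without clonotypes with a count of 1, the TRB richness difference reversed to 275, TRB entropy differed by -0.0998, the TRB share of the 100 most abundant by 6.60 and TRA richness by -776, none of them past the threshold, while the TRA CDR3 length difference, 0.0398, passed it. With Chao1 at full depth, which also estimates unseen clonotypes, the richness differences were -31932 for TRB and -13771 for TRA and passed (adjusted exact p = 0.0204 each). Without thinning, and so at unequal depth, differences of -2474 in TRB richness, -0.355 in TRB entropy and -4335 in TRA richness did not pass. Neither did the TRA overlap excess within groups of 0.00259 with the Jaccard index. By usage, 1 TRBV gene and 1 TRBJ gene passed in DESeq2, and 3 TRBV genes and 1 TRAJ gene passed when each distinct clonotype was counted once. The number of TRA clonotypes past the threshold was 3 with TMM and 0 when detected in at least 8 samples. The cause was not tested for any of these.

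Differences not past the threshold that changed direction were, weighted by count, -0.00373 in TRA CDR3 length, -0.00893 in TRB CDR3 length and -0.0423 in the TRB doublet share; 0.3 in TRB clonotypes shared by all 5 samples; -0.00306 in the TRB overlap excess by nucleotides; 0.0902 in the MAIT-associated TRBV share of distinct clonotypes; 0.00815 in the TRB cysteine share without TRBV1; and 0.0616 in the share of TRAJ genes at the 3' end without both libraries of the sharing pair. With 1 sample left out these differences ranged through 0: the mean TRAJ number from -0.115 to 0.113, the TRB cysteine share from -0.362 to 0.0177, TRB CDR3 length from -0.00122 to 0.0173 and the share of TRAJ genes at the 3' end from -0.673 to 0.364. Log2 fold changes that changed direction with each distinct clonotype counted once were -0.0609 for TRBV31, -0.0465 for TRBV26, 0.0846 for TRBV13-2, 0.00162 for TRBJ2-7, -0.0557 for TRAJ31, -0.0581 for TRAJ12 and -0.0408 for TRAJ30; without both libraries of the sharing pair, -0.0456 for TRBV19 and -0.0581 for TRAJ31; and with the J names as deposited, 0.00591 for TRBJ2-5. With 1 sample left out they ranged from -0.0120 to 0.177 for TRBV31, -0.00476 to 0.169 for TRBV19, -0.00938 to 0.164 for TRBV26, -0.111 to 0.0194 for TRBV1, -0.0752 to 0.00184 for TRBJ2-7, -0.0721 to 0.0718 for TRAJ31, -0.0208 to 0.068 for TRAJ12, -0.0220 to 0.0840 for TRAJ30 and -0.0345 to 4.16 for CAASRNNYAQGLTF of TRAJ26. The cause was not tested.

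Leaving out 1 sample gave 9 to 54 TRA clonotypes past the threshold, an excess of TRA overlap within over between groups of 0.0189 to 0.0818, a TRB excess of -0.00411 to 0.0101, a TRB share difference of 4.65 to 6.42, 0 to 2 TRBV genes and 0 to 1 TRBJ gene. The TRA excess did not pass without any single CNS4Flox replicate, and the TRB share did not pass without CNS4Flox replicate 1, 2, 4 or 5. Leaving out a CNS4Flox sample leaves fewer CNS4Flox than CNS4KO pairs in the pooled mean within groups, which by itself lowers the TRA and TRB excess. Leaving out a CNS4KO sample raises it in the same way. These changes in the excess therefore do not by themselves show dependence on single samples. Log2 fold changes ranged from -0.0704 (without CNS4KO replicate 1) to 7.88 for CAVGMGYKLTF of TRAJ9, from -1.67 (without CNS4KO replicate 1) to 6.48 for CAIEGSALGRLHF of TRAJ18, and from -6.10 to 0.29 (without CNS4Flox replicate 5) for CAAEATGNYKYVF of TRAJ40; each reversed without the library that holds most of its counts. Without both libraries of the sharing pair the differences were -3066 and -6411 in TRB and TRA richness, -0.45 and -0.90 in entropy, 6.77 and 12.2 in the shares, -2057 in shared TRA clonotypes and 0.0615 in the TRA overlap excess, all in the direction of the full set; groups of 4 allow no p below 0.0286, so these say nothing about the threshold. That set gave 42 TRA clonotypes. The carry-over filter moved no TRB overlap or shared TRB clonotype, so it tests nothing there. No paired analysis was possible because the labels give no shared replicate numbers. Settings fixed in advance for alpha V gene usage, alpha inserted bases, the MAIT alpha chain, non-productive shares and the lists of TRAV, shared alpha and delta, and gamma or delta genes were not run. The median TRB clonotype had a count of 1 in every sample, which limits comparisons of single clonotypes.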

Other observations

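The test of inserted bases in this part was chosen only after the result was seen. Sharing of clonotypes over both groups together was counted for each chain, but TRB clonotypes were defined with a V gene and TRA clonotypes without one, and TRA had 482226 counts against 266347 for TRB, so the chains are not directly comparable. Of the TRB amino acid clonotypes 146889 were found in a single library, holding 75.5% of TRB counts, and 2 were found in all 10, holding 0.0225%. Of the TRA amino acid clonotypes 49229 were found in a single library, holding 20.9% of TRA counts, and 883 were found in all 10, holding 20.6%. TRA clonotypes of all 10 libraries were encoded by 2.78 nucleotide variants per library on average, against 1.02 for those of a single library, and had 13.1 residues on average, against 13.99. TRB clonotypes of a single library had 4.21 inserted bases on average, those of 3 to 7 libraries 2.24 and those of all 10 libraries 1.29.

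Sharing of TRB clonotypes among Treg samples may rest on recombination with few inserted bases, which makes the same receptor likely to arise repeatedly. In all 10 libraries, TRB clonotypes found in at least 3 libraries had fewer inserted bases than those found in 1 library (two-sided exact sign-flip p = 0.00195, the smallest that 10 libraries can give). This repeats by library the pooled pattern that prompted the hypothesis, and so adds no independent evidence for it.

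The lower TRA overlap among CNS4KO samples could come from counts moving from widely shared to private clonotypes. The test left this open: clonotypes found in at least 8 libraries held 35.8% ± 2.94 of TRA counts in CNS4KO and 36.0% ± 1.41 in CNS4Flox (SD, n = 5 each; exact permutation p = 0.905). The criterion set in advance against it, an exact p of at least 0.05, was too weak, since such a p does not show that the shares are equal, and the alternative that different clonotypes are expanded in each CNS4KO sample was not tested separately.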
